A study of Mus musculus with 6 samples.

How the data were processed

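Polyadenylated RNA was measured by bulk RNA sequencing in group 2 innate lymphoid cells (ILC2) sorted from mouse visceral adipose tissue, in 3 adult and 3 old C57BL/6 libraries. Per the labels, reads were paired-end and 101 bp long. The deposited file holds whole-number read counts per gene for each library, with Ensembl gene identifiers and symbols. Per the submitters' processing notes, the tools named were STAR 2.7.3a, HTSeq, DESeq and DESeq2, and the genome build was mm10. Their settings, the annotation release and whether HTSeq counted by strand are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping gene on the other strand cannot be told apart. Genes with near-identical copies may gain or lose reads to these copies.

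The counts were used as deposited. Of 56221 rows, 25 repeated the identifier of another row with counts of 0 throughout and were removed, which left 56196 genes. Library totals ran from 14455771 counts in adult 2 to 16940413 in old 3. A floor of 3 counts corresponded to 0.177 to 0.208 CPM, counts scaled to the library total. The reads carried no molecular identifiers, so this floor covers counting error only. Libraries were grouped by the age stage in the labels. The labels number 3 samples per group without stating that each came from a separate mouse, so the p-values measure the spread between these samples, which may be technical. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 18.6 between any pair.

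Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by group, which kept 14740 genes, and libraries were scaled by TMM factors. The quasi-likelihood F-test compared old with adult mice, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Log2 fold changes are given as old over adult, with the standard error (SE) derived from the F statistic. CPM values are given as mean ± SD of 3 libraries per group, scaled by the TMM factors. Of the tested genes, 14729 were found in the GENCODE M21 annotation, whose GRCm38 assembly is the mm10 build, and gene positions are given from it.

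A total of 33 gene lists was fixed before the data were examined, covering ILC2 programs, other cell types and signs of RNA quality. Each list with at least 3 tested genes was compared with the remaining genes by camera (limma 3.58.1), two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists. The same test with the correlation estimated from each list, and the rotation test fry, were run beside it. Summed CPM of the lists of other cell types were compared by an exact two-sided permutation test over 20 assignments, whose smallest possible p is 0.1.

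The genes named were set by a rule written before the data were examined. They were, first, up to 10 genes per direction with the smallest adjusted p among those past the threshold, with no overlap between the groups, a mean of at least 5 CPM and a symbol that is not a clone or pseudogene name. Second came a fixed set of ILC2 and senescence genes, named whatever their result. Last came up to 4 members with the smallest p in each list spoken of. The genes Hip1r, Gmpr2, Sds, A830012C17Rik and Gpx4-ps2 are given because they overlap or copy a named gene, and were chosen after their values were seen. Other named genes also overlap genes on the other strand, among them Nfkbib (Sirt2), Kdm6b (Kdm6bos), H2-Eb1 (Gm20513) and Cyp51 (Akap9). Any other gene outside the rule is said to have been chosen after its values were seen.

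The procedure was tested on simulated data for the comparison of old with adult mice, with 14092 genes tested and no GC trend. It called 97 genes, of which 6 (6.19%) were false. The simulated changes were given only to genes of at least 5 mean CPM. Of these genes the procedure recovered 1.49% of those changed 1.5-fold, 46.3% of those changed 2-fold and 89.4% of those changed 4-fold. Changes below 2-fold were therefore mostly not detectable with 3 libraries per group. With a simulated trend (Spearman correlation of 0.596 between transcript GC content and the log2 fold change of unchanged genes) it called 218 genes, of which 111 (50.9%) were false, and after the GC correction 97, of which 8 (8.25%) were false. In the real comparison, which was not corrected for GC content, the correlation over the tested genes was 0.184.

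The alternatives planned before the data were examined covered other scaling factors, the DESeq2 1.42.0 Wald test and limma-voom with sample weights. Others changed the low-count filter, thinned every library to the smallest total, used the title number as a block, or used an adjusted p under 0.1. The last ones set a minimum fold of 1.5 and left out each library in turn. Corrections for transcript GC content, for transcript length and for the level of B cell genes were added after the data were seen. Their effects are given in the closing section. No library was left out of the main comparison.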

Results

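ILC2 are tissue lymphocytes without antigen receptors that produce type 2 cytokines and, in fat, respond to the alarmin IL-33. All mice of the series, adult and old, had received IL-33 by intraperitoneal injection once a day for 5 days and were then rested for 6 weeks. ILC2 were sorted from the visceral fat of these mice, and 3 adult and 3 old libraries were sequenced. Total counts were 16635856, 14455771 and 15847902 in adult 1, 2 and 3. They were 16426403, 16634868 and 16940413 in old 1, 2 and 3. Pearson correlations of log2 CPM were 0.914 to 0.947 between adult libraries and 0.935 to 0.945 between old libraries. Between the groups they were 0.907 to 0.944. Adult 2 stood apart from the other 5 libraries on the first principal component, which held 32.2% of the variance.

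The comparison asked how ILC2 from the fat of old mice differed from those of adult mice after the same course of IL-33. In old mice, 7 of 20 tested genes of the NF-kB list were higher, among them Nfkbia (2.59-fold), Icam1 (2.63-fold) and Nfkbie (2.501-fold), and 13 did not pass. Of the genes of antigen presentation, 4 of 15 for MHC class I and 2 of 11 for class II were higher. These 3 lists passed by camera with a preset correlation and not with an estimated one (adjusted p = 0.118, 0.118 and 0.255). Fewer genes were lower in old mice, led by the lactate dehydrogenase subunit Ldhb, the arginine synthesis enzyme Ass1 and the T cell receptor complex subunit Cd3g. The genes that define ILC2, such as Gata3, Il1rl1 and Klrg1, did not pass the test. Of 14740 genes tested, 115 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group), with 102 higher and 13 lower in old mice.

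The gene with the smallest adjusted p was Vmn2r100, a vomeronasal receptor gene at chromosome 17, 19504732 to 19535231 on the plus strand (mm10). Its level was 68.9 ± 12.2 CPM in adult and 514 ± 29.9 CPM in old mice (log2 fold change 2.90, SE 0.16, edgeR adjusted p = 0.000544). This gene belongs to a family of similar copies, so the origin of its reads is uncertain. The labels give the strain of all mice as C57BL/6 without a substrain or supplier, so a genetic difference between the adult and old mice at Vmn2r100 or Vps37b was not excluded. Vps37b, a subunit of the ESCRT-I sorting complex at chromosome 5, 124004641 to 124032270 on the minus strand, rose from 77.0 ± 3.38 to 439 ± 69.9 CPM (log2 fold change 2.51, SE 0.14). The gene Hip1r overlaps it on the other strand and was also higher (log2 fold change 1.49, SE 0.21), so the reads of this pair cannot be assigned with certainty. Ccdc184, on chromosome 15, rose 2.79-fold. Tinf2, a component of the telomere-capping shelterin complex on chromosome 14, rose 3.96-fold from 24.97 ± 5.21 to 99.0 ± 7.76 CPM. It overlaps Gmpr2 on the other strand, which did not pass the test (log2 fold change -0.21). Kdm6b, a histone H3K27 demethylase, rose 2.28-fold, and Pde4b, a cAMP phosphodiesterase, rose 2.13-fold. Lmo4, a LIM-domain transcription cofactor, rose 1.97-fold. As the rule for naming required, all 3 old libraries lay above all 3 adult libraries for each gene it named here.

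Among the genes lower in old mice, 9 met the rule for naming. Ldhb, which encodes the heart-type lactate dehydrogenase subunit (chromosome 6, 142490249 to 142507957), fell from 55.7 ± 8.31 to 21.4 ± 2.01 CPM (log2 fold change -1.38, SE 0.17, edgeR adjusted p = 0.0272). Ass1, argininosuccinate synthase (chromosome 2, 31470207 to 31520672), fell from 179 ± 2.02 to 93.7 ± 6.28 CPM. Cd3g (chromosome 9, 44969572 to 44980431) fell from 326 ± 80.3 to 118 ± 16.6 CPM (log2 fold change -1.47, SE 0.19). The integrin beta-1 gene Itgb1 changed by a log2 fold change of -1.32, and Cd96, a receptor of the nectin-binding family, by -0.74. Epha7, an ephrin receptor, fell from 13.3 ± 2.32 to 1.30 ± 1.11 CPM, and Nyap2 from 11.6 ± 3.80 to 1.34 ± 0.937 CPM. The remaining 2 were Plbd2 (log2 fold change -1.78), which overlaps the gene Sds on the other strand, and Zfp410 (-0.75).

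**Figure D1:**
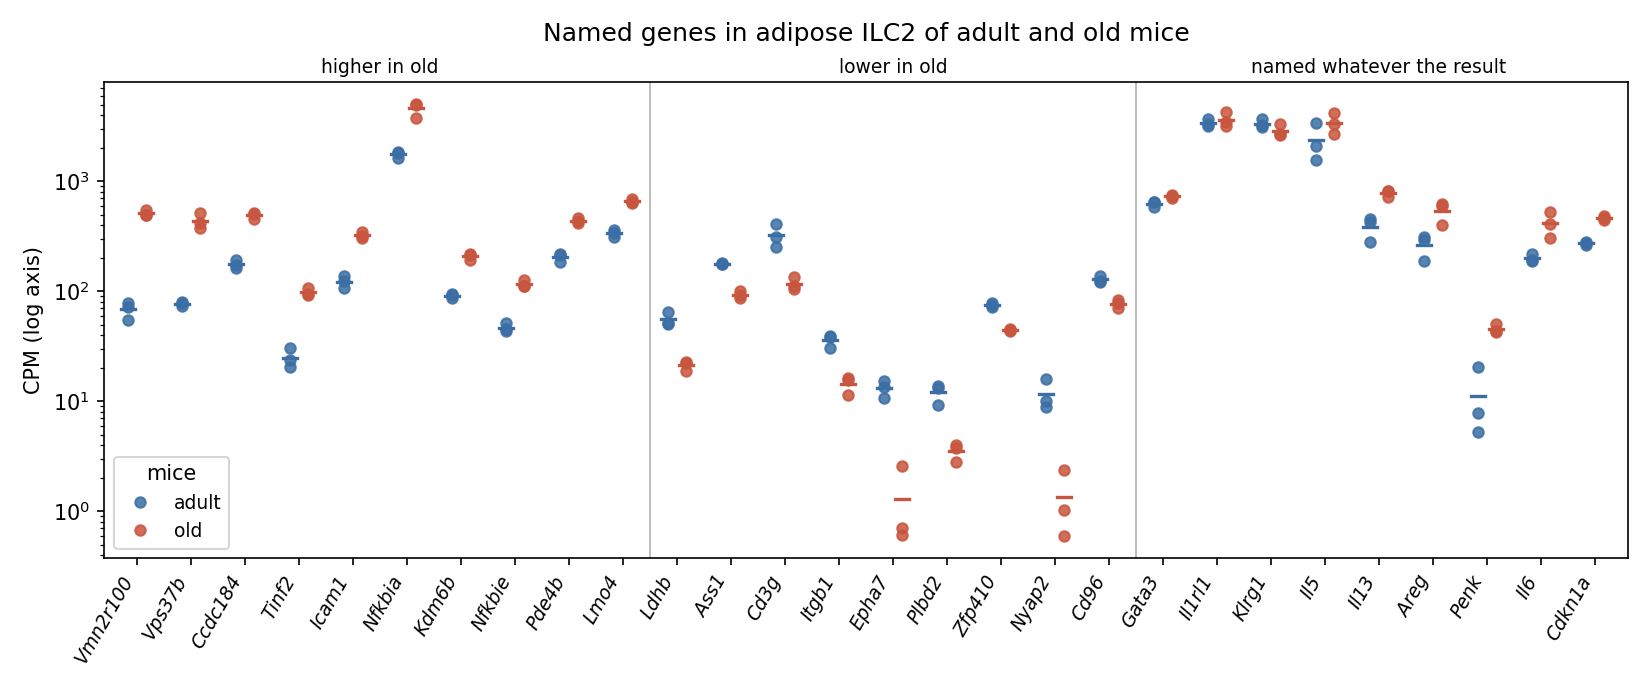
CPM on a log axis of 28 named genes in each of the 3 adult (blue) and 3 old (red) libraries, with points for libraries and bars for group means. Points of the groups do not overlap for the genes named as higher or lower, as the rule for naming required, while Il1rl1 and Klrg1 have overlapping values.

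None of the 115 called genes had overlapping values between the groups. Over all tested genes 22.7% had groups without overlap, where chance gives 10%. The count of changed genes varied with the library left out. It was 6 without adult 1, 3 without adult 2, 2 without adult 3, 239 without old 1, 2 without old 2 and 14 without old 3. All 115 kept their direction in each of these fits. A smaller fit also has less power, so the counts alone do not show dependence on a particular library. The count was 897 with the DESeq2 Wald test, 215 with limma-voom, 216 with no low-count filter, 424 among genes of at least 5 mean CPM and 4 against a minimum fold of 1.5.

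The NF-kB list held 20 tested genes, of which 7 rose and 13 did not pass (15 rose when adjusted over the list alone). Log2 fold changes were positive in all 20. They were small for Tnfaip3 (0.06, SE 0.09), Nfkbiz (0.07, SE 0.12), Tnf (0.07, SE 0.23) and Il1b (0.05, SE 1.08). Tnfaip3, Nfkbiz, Tnf and Il1b were chosen after their values were seen. Nfkbia encodes the inhibitor IkB-alpha, a target of NF-kB, at chromosome 12, 55489410 to 55492647 on the minus strand. It rose from 1777 ± 116 to 4606 ± 701 CPM (log2 fold change 1.37, SE 0.13, edgeR adjusted p = 0.00818). The adhesion molecule gene Icam1, at chromosome 9, 21015985 to 21028817, rose from 123 ± 14.5 to 323 ± 20.6 CPM. The inhibitor genes Nfkbie and Nfkbib rose 2.501-fold and 4.41-fold. The list had a median log2 fold change of 0.79 (camera adjusted p = 3.73e-25). It did not pass with an estimated correlation (adjusted p = 0.118) and passed the rotation test fry (adjusted p = 0.0137).

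Genes of MHC class I presentation were higher as a list by camera with a preset correlation (adjusted p = 3.70e-10) and not with an estimated one (adjusted p = 0.118). Of 15 tested members 4 rose and 11 did not pass (7 rose when adjusted over the list alone). H2-D1, a classical class I heavy chain, rose from 1366 ± 37.3 to 4292 ± 1517 CPM, with old 1 at 2540 CPM, old 2 at 5152 CPM and old 3 at 5183 CPM. H2-Q7 rose 1.88-fold and H2-K1 1.51-fold, and Nlrc5, the transactivator of class I genes, rose 1.64-fold. For class II presentation 2 of 11 members rose and 9 did not pass (7 rose when adjusted over the list alone). H2-Eb1, a class II beta chain, rose from 40.8 ± 11.5 to 138 ± 45.6 CPM, and H2-DMb1, a chain of the peptide-loading molecule, from 2.48 ± 0.354 to 10.2 ± 3.28 CPM. H2-Ab1 had 10.1 ± 2.81 against 97.8 ± 62.8 CPM and narrowly missed the threshold (edgeR adjusted p = 0.0508). The class II list had a camera adjusted p of 4.09e-08, and adjusted p = 0.255 with an estimated correlation. The H2 genes are close paralogs, so reads may be divided unevenly among them.

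Other measured features were set beside these lists. The summed CPM of B cell genes was 763, 2533 and 1530 in old 1, 2 and 3, against 1008 to 1259 in adult mice (exact permutation p = 0.5). Class II genes were also highest in old 2. The B cell sum was lowest in old 1, where class II genes still stood above adult libraries (mean log2 CPM 3.91 against 3.37 to 3.48). The same held for NF-kB genes (7.27 against 6.51 to 6.78). Transcript GC content was ranked over the 6359 genes with a mean log2 CPM above 4. The 10% of them highest in GC content deviated by -0.17 to -0.05 (log2) from their mean level in adult libraries and by 0.02 to 0.21 in old libraries. The median GC content was 53.6% for the NF-kB list, 55.0% for class I and 54.3% for class II, against 48.9% for genes not called.

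Of the type 2 cytokines and effectors, 2 of 17 tested genes rose and 15 did not pass. Adjusted over the list alone, 10 rose and 1 fell. Furin, a proprotein convertase, rose 2.28-fold and the cytokine gene Lif rose 2.38-fold, from 168 ± 39.0 to 398 ± 25.8 CPM. Il13, a hallmark ILC2 cytokine, had 389 ± 96.1 CPM in adult and 791 ± 54.9 CPM in old mice and did not pass (log2 fold change 1.023, SE 0.18, edgeR adjusted p = 0.0515). Il6 had 200.5 ± 15.1 against 415 ± 110.4 CPM (adjusted p = 0.0546). The epidermal growth factor family ligand Areg had a log2 fold change of 1.03 and Penk, which encodes an enkephalin precursor, one of 2.02 (edgeR adjusted p = 0.0872 and 0.0869). Penk overlaps A830012C17Rik on the other strand, which did not pass either (log2 fold change 2.51, edgeR adjusted p = 0.0736), so the reads of this pair cannot be assigned with certainty. For Il13, Il6, Areg and Penk all old libraries lay above all adult libraries. Il5 (log2 fold change 0.53, SE 0.27) and Csf2 (0.14, SE 0.24) overlapped between the groups. The list stood higher with a preset correlation (camera adjusted p = 5.44e-09) and not with an estimated correlation (adjusted p = 0.255).

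The ILC2 identity list held 21 tested genes, and none passed, also when adjusted over the list alone (camera adjusted p = 0.447, edgeR). Of the 21, 8 had positive log2 fold changes. The transcription factor genes Gata3 and Rora had log2 fold changes of 0.22 (SE 0.10) and 0.43 (SE 0.13). The IL-33 receptor gene Il1rl1 was at 3418 ± 258 CPM in adult and 3626 ± 558 CPM in old mice. Klrg1 (-0.21), Il7r (-0.14), Icos (-0.10) and Arg1 (-0.22) also had small log2 fold changes that did not pass. Il2ra (0.39, SE 0.13), Tcf7 (-0.57, SE 0.21) and Gfi1 (-0.86, SE 0.36) had larger ones that did not pass either. Changes below 2-fold were mostly not detectable, so the identity genes were not shown to be unchanged. Among receptors for neuropeptides, hormones and lipid mediators, 1 of 15 rose, the adenosine receptor gene Adora2a, from 9.43 ± 0.968 to 46.0 ± 21.04 CPM (6 rose when adjusted over the list alone). The leukotriene B4 receptor gene Ltb4r1 had a log2 fold change of 1.93 and did not pass (edgeR adjusted p = 0.0658). The receptor list had a camera adjusted p of 0.0108, and adjusted p = 0.255 with an estimated correlation.

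Of the senescence and secretory list, 1 of 19 genes rose (2 when adjusted over the list alone). This was Cdkn1a, which encodes the cell cycle inhibitor p21, from 275 ± 8.14 to 464 ± 19.9 CPM (log2 fold change 0.76, SE 0.10, edgeR adjusted p = 0.0276). Cdkn2a was not tested, with 1 to 4 counts per library. The proliferation gene Mki67 had a log2 fold change of -0.78 (SE 0.48), and no cell cycle gene passed among 17 (camera adjusted p = 0.913). Of 25 immediate early genes 2 rose, the nuclear receptor genes Nr4a1 and Nr4a3, by 2.41-fold and 1.61-fold (9 rose and 1 fell when adjusted over the list alone). Fosl2 and Zfp36 had log2 fold changes of 0.67 and 0.48 and did not pass. The senescence and immediate early lists had camera adjusted p of 0.0113 and 0.00117, and adjusted p = 0.255 each with an estimated correlation.

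In 3 further lists a single gene rose. Isg15 was the only one of 17 interferon response genes to rise, 1.85-fold (camera adjusted p = 0.0489 for the list; adjusted p = 0.255 with an estimated correlation). Srebf2, a regulator of sterol synthesis genes, was the only one of 19 in the cholesterol and fatty acid synthesis list, at 2.03-fold (4 rose when adjusted over the list alone). Sqle and Cyp51, which encode sterol synthesis enzymes, had log2 fold changes of 1.17 and 0.93 and did not pass. Herpud1, an endoplasmic reticulum stress gene, was the only one of 19 unfolded protein response genes, at 1.52-fold. These 2 lists had camera adjusted p of 0.0113 and 0.0231, and adjusted p = 0.475 and 0.382 with an estimated correlation. No member passed in the lists of survival genes (18 tested, with 8 rising when adjusted over the list alone) and of inhibitory receptors (16 tested, 3). Their camera adjusted p were 0.00117 and 0.0292, and adjusted p = 0.255 and 0.373 with an estimated correlation. Pdcd1, which encodes PD-1, had 1268 ± 186 against 1937 ± 311 CPM without passing (edgeR adjusted p = 0.112).

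Cytosolic ribosomal protein genes stood lower in old mice as a list by camera with a preset correlation (adjusted p = 2.11e-09) and not with an estimated one (adjusted p = 0.446), with 25 of 26 log2 fold changes below 0 and a median of -0.34. No single member passed over all genes, and 16 fell and 1 rose when adjusted over the list alone. Rplp0 had 4023 ± 394 CPM in adult and 3054 ± 17.8 CPM in old mice, while Rpl13 had a log2 fold change of 0.58. The 13 mitochondrially encoded respiratory chain genes all had log2 fold changes below 0, with a median of -0.21 and no member past the threshold. Camera gave an adjusted p of 0.0205 for this list, and adjusted p = 0.733 with an estimated correlation. The share of counts from mitochondrial genes was 2.79% to 3.75% in adult and 2.59% to 2.98% in old libraries. Lists of glycolysis, fatty acid handling, nuclear-encoded respiratory chain, antioxidant and homing genes did not pass (camera adjusted p of 0.447, 0.955, 0.913, 0.181 and 0.921). Within them the antioxidant enzyme gene Gpx4 rose 1.83-fold and the homing gene Itgb1 fell. The values of Gpx4 may include reads of a pseudogene copy.

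**Figure D2:**
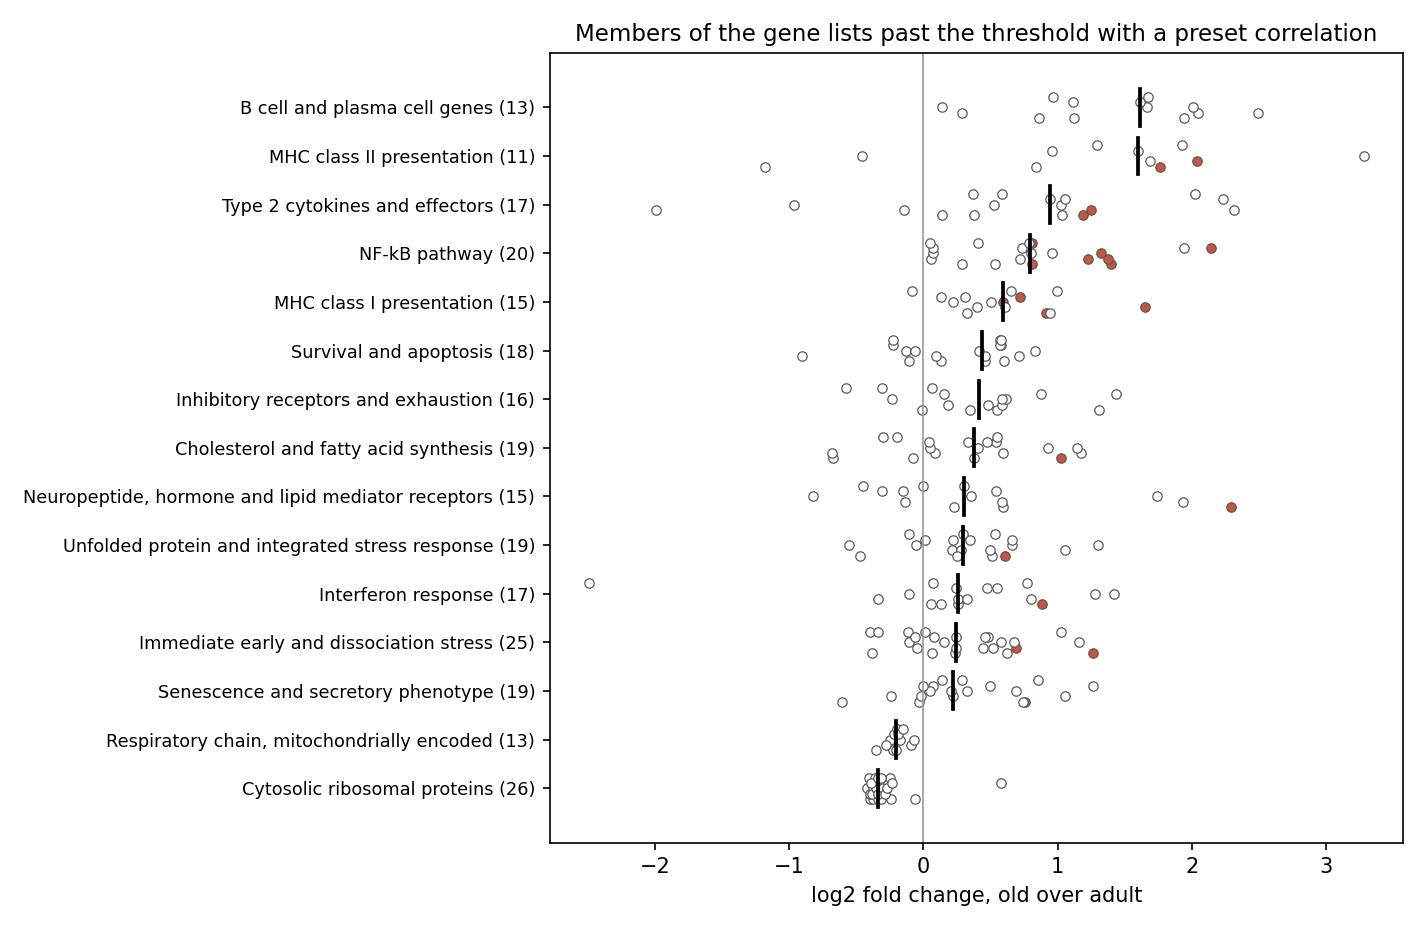
Log2 fold changes, old over adult, of the tested members of the 15 lists past the threshold with a preset correlation, with the number of tested genes in brackets. Each circle is a gene, filled red where it rose (edgeR adjusted p under 0.05), and each black line is the list's median. The NF-kB list has 7 filled circles, and the medians of the ribosomal and mitochondrial lists lie below 0.

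With the preset correlation of 0.01, 15 of 33 lists passed, 13 higher and 2 lower in old mice. With estimated correlations 0 passed. With fry 3 passed, the NF-kB, MHC class I and, without a camera call, type 1 ILC and NK cell lists, all 3 as higher in old mice. At an unadjusted p under 0.05, 2293 single genes differed by edgeR, 1362 higher and 931 lower in old mice.

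Genes of other cell types were measured to describe what the sorted libraries held. The B cell and plasma cell list stood higher in old mice with the preset correlation, and none of its 13 tested genes passed (camera adjusted p = 0.000426; adjusted p = 0.446 with an estimated correlation). Cd79a, a part of the B cell receptor, had 11.2 ± 3.51 against 43.0 ± 22.5 CPM. The summed T cell genes were 1713 ± 128 CPM in adult and 1373 ± 103 CPM in old mice. The exact permutation p was 0.1, the smallest possible, and 0.55 when adjusted over the lists of other cell types. The T cell list did not pass (camera adjusted p = 0.112). Its sum includes Cd3g, the only called member, at 326 CPM in adult and 118 CPM in old mice. Of the 10 tested T cell genes, 4 had positive log2 fold changes. Dendritic cell genes summed to 30.7 ± 2.48 and 55.4 ± 11.6 CPM (exact permutation p = 0.1, adjusted p = 0.55), with a camera adjusted p of 0.156. Granulocyte and mast cell genes reached 724 CPM in old 2 against 285 to 402 in the other libraries. One member of that list, the IgE receptor subunit gene Fcer1a, rose 7.70-fold, while the mast cell protease gene Cma1 did not pass (log2 fold change 0.55, SE 0.51). Macrophage genes summed to 3978 ± 196 and 3464 ± 383 CPM, of which 98.0% came from the chemokine receptor gene Ccr2. In the list of type 1 ILC and NK cell genes, 6 of 9 tested members had positive log2 fold changes. Its member Nkg7 had 9.04 ± 2.79 CPM in adult and 22.6 ± 2.66 CPM in old mice without overlap and did not pass (edgeR adjusted p = 0.0732), and Ifng had 1.42 ± 0.297 and 0.757 ± 0.920 CPM. That list, and those of type 3 ILC, macrophages, granulocytes, adipocytes, fibroblasts, endothelium and red cells, did not pass (camera adjusted p from 0.447 to 0.955). The 4 tested Y-linked genes did not pass and were expressed in all libraries.

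**Figure D3:**
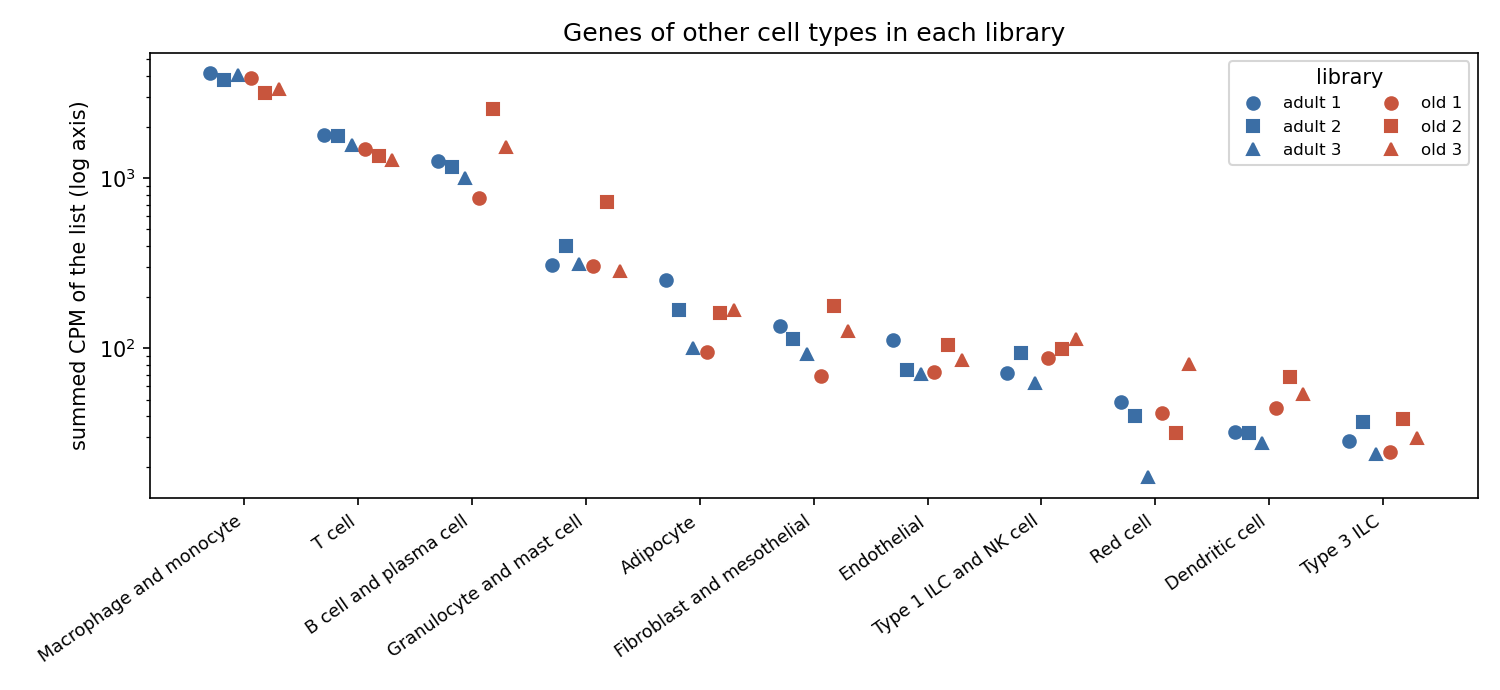
Summed CPM, on a log axis, of the genes of 11 other cell types in each of the 6 libraries, with blue for adult, red for old and a marker shape for each replicate. Old 2 has the highest sums of B cell (2533 CPM) and of granulocyte and mast cell genes (724 CPM).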

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

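The corrections for GC content, transcript length and B cell level were chosen after the data were seen; the other alternatives were planned. The cause of a change was not tested unless stated. Against 115 genes changed, 102 higher and 13 lower in old mice, the DESeq2 Wald test gave 897, 653 and 244, limma-voom with sample weights 215, 190 and 25, and no low-count filter 216, 196 and 20. A mean of at least 5 CPM, with 9502 genes tested, gave 424, 367 and 57, and an adjusted p under 0.1 gave 376, 322 and 54. Testing against a 1.5-fold change gave 4, 4 and 0, the GC correction 73, 68 and 5, and the B cell level as a covariate 2, 2 and 0. Total counts without factors gave 8 lower genes. DESeq2 size factors, upper-quartile factors, thinning and the length correction kept the total within 1.5 times, from 87 to 133. Leaving out 1 library gave 2 to 239 changed, 2 to 225 higher and 0 to 14 lower genes; 96 of the 115 were shared without old 1, and 2 to 13 without any other library. All 115 kept their direction in each of these settings that tested them. Each scaling moved the median log2 fold change of all tested genes by under 0.1 (log2). Of the 115 genes, the DESeq2 Wald test shared 113, and its higher genes made 72.8% of its calls against 88.7%.

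Title numbers 1 to 3 recur in both groups. Libraries with the same number had correlations of their deviations from the group means of 0.09, -0.03 and -0.02, and of the 6 libraries only old 1 correlated best with the library of its own number, so the numbers were not taken to pair libraries. With the title number as a replicate block, edgeR gave 2 genes changed, 2 higher (Vmn2r100 and Vps37b) and 0 lower, with 1950 genes at an unadjusted p under 0.05, and all 115 kept their direction. The block turned the sign of Uty (0.0349) and of the macrophage list (-0.162).

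Of 33 lists, 15 changed; 9 did with the B cell level as a covariate, 0 with estimated correlations and 3 with fry. Over the lists, 518 of 623 values kept their direction and side of the threshold, 59 lost a call, 5 gained one and 41 turned direction. For the 157 named genes, 2339 of 2788 kept both, 281 lost a call, 122 gained one and 46 turned direction. Of the values that turned, 36 of lists and 46 of genes passed in neither setting. Vmn2r100 and Vps37b passed in all 18 alternatives. Without the most abundant gene of its list, the difference between the group means of log2 summed CPM moved from 0.05 to 0.80 for type 3 ILC, from -0.20 to -0.41 for macrophage and from 0.04 to -0.42 for endothelial genes, each by more than 1 SD between replicates. The other 8 lists of cell types stayed within 1 SD, with B cell genes from 0.33 to 0.55, and adipocyte (-0.24 to 0.12) and fibroblast genes (0.05 to -0.40) turning sign. The macrophage value rests on old 1, with sums of 14.8, 193 and 40.6 CPM in old 1, 2 and 3 against 59.9 to 78.4 in adult libraries.

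The values that turned were log2 fold changes of genes or list medians, with the direction of a list taken from camera, or from fry in its own setting. The value given for fry is the list's median in the main fit. With upper-quartile factors these were Cd209a (-0.0118), Kdm5d (-0.0237) and fatty acid handling (-0.0255). With limma-voom they were Zbtb46 (-0.0461), Uty (0.111), adipocyte (-0.0128) and homing genes (-0.0490). With at least 5 CPM they were macrophage (0.0579), adipocyte (0.268), fibroblast (-0.187), cell cycle (0.1198) and fatty acid handling genes (-0.0222). With thinning they were Zbtb46 (-0.0108), Cd209a (-0.221) and macrophage genes (0.446). The GC correction turned Uty (0.109), the length correction Cd209a (-0.0316), fatty acid handling (-0.0537) and homing genes (-0.0454), and fry adipocyte genes (-0.144). The B cell covariate turned the genes Il7r (0.0992), Icos (0.144), Cxcr5 (-0.681), Lat (-0.0393), Ighd (-0.276), Apoe (-1.018), Cd68 (-0.790), Cd209a (-3.43), Cma1 (-0.535), Mcpt8 (-1.64), Lipe (-0.157), Gsn (-0.00554), Upk3b (-0.891), Cd34 (-0.721), Eif2s3y (0.268), Kdm5d (-0.0384) and Uty (0.353). It also turned the lists of ILC2 identity (0.0992), B cells (-0.276), macrophages (-1.018), granulocytes (-1.44), fibroblasts (-0.878), cell cycle (-0.0234), nuclear-encoded (-0.0682) and mitochondrially encoded respiratory chain genes (0.0318).

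Leaving out 1 library turned 11 genes and 11 lists. Their ranges were -0.553 to 0.622 for Cd209a, -0.884 to 2.03 for Cd68, -0.400 to 0.882 for Cma1, -0.0479 to 0.436 for Csf2, -0.345 to 0.00867 for Eif2s3y, -0.221 to 0.896 for Hbb-bs, -0.0292 to 0.176 for Il1rl1, -0.0942 to 0.219 for Kdm5d, -2.01 to 0.104 for Tek, -0.162 to 0.305 for Uty and -0.106 to 0.250 for Zbtb46. For lists they were -1.42 to 0.111 for adipocyte, 0.0395 to 0.198 for cell cycle, -0.5999 to 0.639 for endothelial, -0.00509 to 0.0598 for fatty acid handling, -0.229 to 0.891 for fibroblast, -0.420 to 0.627 for granulocyte, -0.0400 to 0.123 for homing, -0.884 to 1.21 for macrophage, -0.221 to 0.816 for red cell, -0.160 to -0.0547 for nuclear-encoded respiratory chain and -0.0999 to 0.262 for sex-linked genes. In simulated data with 3 libraries per group, 1.49% of 1.5-fold and 46.3% of 2-fold changes were recovered among genes of at least 5 mean CPM. Thinning all libraries to the smallest total left 133 genes changed.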

Other observations

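Further genes changed in old mice outside the lists and the rule for naming, and the following, apart from the list members Fcer1a and Gpx4, were chosen after their values were seen. The inflammatory caspase genes Casp1 and Casp4 rose 1.98-fold and 3.20-fold, to 254 ± 50.8 and 197 ± 53.6 CPM (edgeR adjusted p = 0.0470 and 0.0272). Ifngr1, which encodes the ligand-binding chain of the interferon-gamma receptor, rose from 249 ± 29.9 to 476 ± 10.9 CPM. Tnfrsf1b, which encodes TNF receptor 2, rose from 56.5 ± 6.87 to 143 ± 23.3 CPM. The cytokine genes Osm and Tnfsf14 rose 4.39-fold and 1.77-fold. The Fc receptor gamma chain gene Fcer1g rose from 15.0 ± 0.612 to 45.5 ± 6.71 CPM, beside the IgE receptor alpha chain gene Fcer1a, from 7.43 ± 3.20 to 57.5 ± 18.9 CPM. As with every called gene, the groups did not overlap for these 8 genes, with all 3 old libraries above all 3 adult libraries. Gpx4 and its pseudogene copy Gpx4-ps2 rose by similar folds, 1.83 and 1.99, and their reads may not be separable.

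The weighing below covers 3 patterns. Its bootstrap intervals resampled the genes of a set and took them as independent, so they do not measure the spread between libraries. The tests of cells of other types, of handling stress and of GC content as the whole cause of a list's difference were written after the results were seen, and Fos, Nfkb2, Ighm, Igkc and Jchain were chosen after their values were seen. The corrections for GC content, transcript length and B cell level were added after the data were seen, with their bounds written before the results of these tests. Age, the difference the design names, stays open in each pattern as an untested biological explanation.

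The first pattern is that 102 of 115 changed genes were higher in old mice, while the 2293 genes at an unadjusted p under 0.05 split into 1362 higher and 931 lower. The median log2 fold change of the 102 was 1.19, and it was 1.06 (95% bootstrap interval 0.93 to 1.21) after the GC correction and 1.14 (0.999 to 1.23) after the length correction, with 67 and 77 of the 102 still called. Both intervals lay above 0.59, the bound set for each trend as the cause. That bound concerns the fold size of genes called for large folds, so it does not decide the balance of directions. Of the genes changed after the GC correction, 68 of 73 were higher in old mice, and 80 of 90 after the length correction. The imbalance remained with either correction, which argues against GC content or transcript length as its whole cause. Cells of other types may have added genes, most of all in old 2, and 21.6% of the 102 were in an other-cell list or rose in old 2 by over 2 times their rise in old 1, with 1 (Fcer1a) in such a list, all 102 above the adult mean in old 1, 29 highest in old 1 and a median rise in old 1 of 88.4% of that in old 2. Since the test that called these genes favours a small spread among the old libraries, these values do not decide, and cells of other types stay open.

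The next pattern is the higher level of the NF-kB list, with a median log2 fold change of 0.79. After the GC correction the median was 0.69 (95% bootstrap interval 0.35 to 0.87), and the list still passed by camera (adjusted p = 1.66e-22; 9.28e-35 to 0.118 over its alternatives, the highest with an estimated correlation), with 6 of its 7 called members still called, while Nfkb2 went from a log2 fold change of 1.22 (SE 0.20) to 0.88 (SE 0.18). The interval lies above 0, which argues against GC content as the whole cause, but it does not lie above 0.40, the bound written beforehand, so a part from GC content stays open. Handling stress of the cells could raise both NF-kB and immediate early genes, and the median of the 25 immediate early genes was 0.24 (0.01 to 0.51), an interval that spans 0.40. In old 1 the mean log2 CPM of immediate early genes was 7.06, within the adult 7.02 to 7.07. NF-kB genes were at 7.27 in old 1, against 6.51 to 6.78 in adult libraries. Fos, the most abundant immediate early gene in adult mice, had 4195 CPM in adult and 3184 CPM in old mice (edgeR adjusted p = 0.109). In the other direction, Nr4a1 had 2800 CPM in adult and 6734 CPM in old mice, and Zfp36 had 3164 and 4415 CPM. A single library and single genes decide nothing for the set, so handling stress stays open.

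The last pattern is the higher level of MHC class II genes, with a median log2 fold change of 1.597 over 11 genes. After the GC correction the median was 1.63 (0.66 to 1.99) and the list passed by camera (adjusted p = 2.64e-07; 4.25e-22 to 0.255 over its alternatives, the highest with an estimated correlation), which argues against GC content as the whole cause, while the interval is not above 0.80, the bound written beforehand, so a part stays open; the calls of H2-Eb1 (log2 fold change 1.76, SE 0.29, to 1.66, SE 0.28) and H2-DMb1 (2.03, SE 0.35, to 1.99, SE 0.34) ended narrowly, at adjusted p = 0.0526, with folds and errors close to those before. B cells carried along in the ILC2 sort may be a source, since by mean log2 CPM both B cell and class II genes were highest in old 2 and old 3, but in old 1 class II genes were at 3.91 against 3.37 to 3.48 in adult libraries, with B cell genes at 3.53, within the adult range of 2.85 to 3.65. The most abundant B cell genes were Ighm, at 429, 963 and 647 CPM in old 1, 2 and 3 and 537 to 670 in adult libraries, Igkc, at 169, 757 and 402 against 181 to 258, and Jchain, at 99.97, 498 and 285 against 219 to 275. With the B cell level as a covariate the class II median was 0.60 (-0.50 to 1.18), an interval that spans 0 and 0.80, while the list passed by camera (adjusted p = 0.0204) with 0 of its 2 called members still called, and old 1 is a single library, so B cells and a change within ILC2 stay open.

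The 6 libraries can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 115 changed genes, 102 in the larger and 13 in the smaller direction, and the highest of the other splits gave 0 in each case. As large a count was reached by 1 split, the real one, for each of the 3 counts. For gene lists the real split gave 15 and the highest other split also 15, so 2 splits gave as many. That other split set adult 1, old 2 and old 3 against the rest, and these 3 libraries had the highest mean log2 CPM of B cell genes, at 3.65, 5.66 and 4.97 against 2.85 to 3.53.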
